A study of Homo sapiens with 4 samples.

How the data were processed

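RNA was sequenced from CD34-positive blast progenitors of 1 patient with secondary acute myeloid leukaemia, in 2 untreated cultures and 2 cultures given 200 nM BC2059 for 8 hours. The sample labels call the libraries of a group biologic replicates. Total RNA was treated with DNase before libraries were made, per the labels' protocols. The submitters' processing notes name TopHat2 2.0 and Cufflinks 2.0 and the build hg19. The annotation, the library kit and its strandedness are not given in the sources used here.

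The deposited table held 1 value per coding gene and library, taken here as FPKM (fragments scaled by transcript length and by the mapped fragments of the library), the unit in which Cufflinks reports. The values themselves showed the authors' quantile normalization, in which values of equal rank are replaced by a mean over libraries. Between 98.3% and 98.7% of a library's values above 1 recurred in another library. Such means were checked by writing values in units of the last of 6 significant digits, the precision assumed for the values that were averaged. In those units 12.7% of the values were whole within 0.01, and 99.6% were once multiplied by 8, as means over 8 libraries would be. Other libraries of that normalization were not used here. The sums of the values were 978712 and 611702 in untreated control replicates 1 and 2, and 574975 and 597382 in BC2059 replicates 1 and 2. The 4 libraries had like medians, from 2.31 to 2.53, and like upper quartiles, from 20.3 to 20.8, whereas their highest values and sums differed. Ranks taken over these rows alone would give equal highest values, and why they differ is not known here. Because this normalization brings the libraries to a like level, a shift of all transcripts together cannot be seen. No counts were given, the depth is unknown, and no interval that needs it was computed.

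The table had 20065 rows. Spreadsheet software had turned 27 gene symbols into dates, and these were restored from the Ensembl identifiers. The 19 second copies of genes shared by both sex chromosomes were left out, and 51 genes were left out of every result for privacy, which left 19995. The 13 mitochondrially encoded genes were listed at no more than 2.10 FPKM, far below their usual level in cells, so their list was not assessed. Only 1 of them, MT-ND3, reached the filter, with a log2 fold change of -0.11 ± 0.33. Metallothioneins had 4 members tested, fewer than the 5 required, and among them MT1E had 0.36 ± 0.32 and MT2A 0.69 ± 0.98. MT1E ranged from 0.03 without BC2059 replicate 2 to 0.68 without BC2059 replicate 1, and MT2A from -0.69 against control replicate 1 alone to 2.06 against control replicate 2 alone.

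Genes with a mean of at least 1 over the 4 libraries (11471) were tested on log2(FPKM + 1), so a fold change is on that scale and understates the change of low genes. Limma 3.58.1 in R 4.3.3 fitted the treatment, with moderated two-sided tests and a trended prior variance, on 2 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Log2 fold changes are BC2059 minus untreated control, followed by their moderated standard error, and FPKM means are followed by the SD of 2 libraries.

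Gene lists (33 in all) were tested with camera from limma, with a preset inter-gene correlation of 0.01, and again with a correlation estimated from the data, and with fry. Adjustment ran over the 31 lists with at least 5 tested members. None of the 20 lists past the threshold stayed past it with an estimated correlation, a version that rests on 2 residual degrees of freedom. By fry, which tests whether a list's genes move one way on balance, 8 of these 20 passed. The other 12 were interferon (adjusted p = 0.0540), progenitors, MYC targets, p53 targets, anti-apoptotic genes and ribosomal proteins (0.0572 each), replication (0.100), B cell markers (0.136), mitosis (0.128), pro-apoptotic genes (0.197), immediate early genes (0.214) and histones (0.268). It passed the T and NK and the cyclin-dependent kinase lists (0.0342), which camera did not. On simulated data the version with an estimated correlation also missed a list of 30 genes shifted by a log2 of 1 (adjusted p = 0.995). Camera with the preset correlation recovered it (adjusted p = 4.81e-19), with 0 of the unshifted lists called. The simulated genes varied independently, so this cannot show how the preset correlation fares where list members vary together. The interferon list had an estimated correlation of 0.64.

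The genes named in the text followed a fixed rule. It took up to 12 genes per direction past the threshold, filled up to 6 by the smallest p where fewer passed. It added 19 genes fixed in advance for the drug target and the disease, whatever their values, and for each list up to 4 members past the threshold, or 2 with the smallest p where none passed. Of the genes this rule takes, 2 are not reported here. ACTB was named after its values were seen. The comparison, the test, the lists, this rule and all but the last 2 of the alternatives that follow were chosen before the data were examined.

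The alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5, cyclic loess and median-of-ratios scaling, limma without the trend or with robust estimation, a test against a fold of 1.2, the replicate number as a block, and leaving out each library in turn. Removing the trend with GC content from each library and estimating library weights were added after the data were seen. No read counts were used, so the planned count-based alternatives were not run. GC content and length came from GENCODE release 29 transcripts, matched by identifier for 98.1% of the tested genes. That release is on another genome build than the authors', so no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.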

Results

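RNA sequencing measured the transcripts of CD34-positive blast progenitor cells from 1 patient whose secondary acute myeloid leukaemia had followed a myeloproliferative neoplasm. CD34 is a surface protein of haematopoietic stem and progenitor cells. The cells were cultured with 200 nM of BC2059, an antagonist of beta-catenin, for 8 hours, or left untreated, with 2 libraries in each group. Beta-catenin is the transcriptional coactivator at the end of the WNT signalling pathway. The single comparison, BC2059 against untreated control, asked which transcripts differ after exposure to the antagonist. Because the 4 libraries came from the cells of 1 patient, p-values measure only the spread between these libraries. The deposited table gave quantile-normalized FPKM values of coding genes and no read counts, so the sequencing depth is unknown. Of 19995 genes kept, 11471 had a mean of at least 1 over the 4 libraries and were tested.

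Genes of the interferon response, of NF-kB and inflammatory signalling and of cholesterol biosynthesis were higher in BC2059-treated cells, as groups, by camera with a preset correlation. Each of these calls was lost with an estimated correlation (adjusted p = 0.221 with an estimated correlation). That version rests on 2 residual degrees of freedom and also missed a simulated list with a true shift. A loss under it therefore decides neither for nor against a call. Markers of haematopoietic progenitors and of the granulocytic, monocytic and erythroid lineages were lower, and so were genes of DNA replication and mitosis. These calls too were lost with an estimated correlation (adjusted p = 0.318 with an estimated correlation for mitosis and 0.221 for the others), and those of replication and mitosis also against control replicate 1 alone (camera adjusted p = 0.133 and 0.128). The median log2 fold change was 2.89 for the interferon list, 2.10 for the NF-kB list, 2.08 for the cholesterol list and -1.38 for the granulocyte list, where 0 means no difference. MYC, a growth-promoting transcription factor, averaged 21.1 ± 1.18 FPKM in BC2059 and 65.5 ± 28.98 in controls (SD, n = 2). No single gene passed limma's test over all genes (0 higher and 0 lower). An unadjusted p under 0.05 was reached by 1302 genes, 622 of them higher and 680 lower, where 573.6 were expected by chance. The controls differed in a way that many genes shared, so this count can stray far from that number without an effect.

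The untreated control replicate 1 stood apart from the other 3 libraries. Across genes its log2 values correlated with theirs at r = 0.854 to 0.899, whereas the other 3 libraries correlated with each other at 0.957 to 0.993 (genes are not independent replicates). The log2 difference between the 2 controls had an SD of 0.898 across genes, against 0.240 between the 2 BC2059 libraries. That difference followed GC content, with a median of -0.52 for genes under 40% GC and 0.98 for genes of 60% GC or more. The next values are set by gene ranks in the quantile normalization, so they are not measured amounts or shares of RNA. In control replicate 1, ACTB, which encodes beta-actin, was listed at 82808 FPKM, against 4386 in control replicate 2. The 10 highest genes held 25.7% of the summed values in control replicate 1 and 6.17% to 7.64% in the other libraries. Values against each control alone are therefore given beside the groups that depend on 1 of them.

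**Figure D1:**
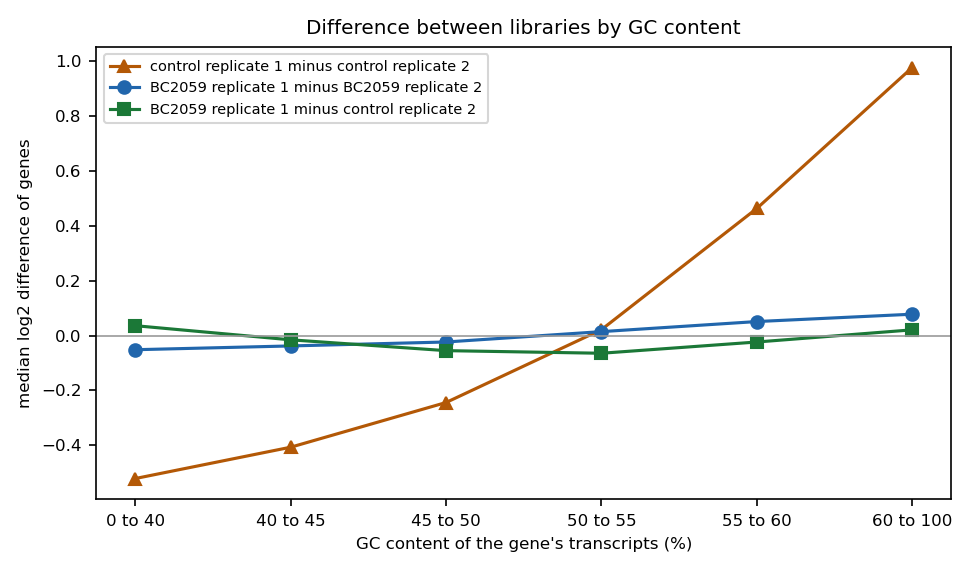
The plot shows the median log2 difference of log2(FPKM + 1) between pairs of libraries (vertical axis) for genes binned by the GC percentage of their transcripts (horizontal axis). The line for control replicate 1 minus control replicate 2 runs from -0.52 to 0.98, and the lines for BC2059 replicate 1 against BC2059 replicate 2 and against control replicate 2 stay between -0.06 and 0.08.

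Among the 32 tested interferon response genes, 31 had a positive log2 fold change (camera adjusted p = 1.04e-32). The call was lost with an estimated correlation (adjusted p = 0.221 with an estimated correlation). Adjusted over the list alone, 31 members passed as higher, against 0 over all genes tested. OAS1, a sensor of double-stranded RNA, averaged 231 ± 76.4 FPKM in BC2059 and 13.6 ± 1.36 in controls (SD, n = 2), a log2 fold change of 3.95 ± 0.31 (SE). IFI44L, another interferon-induced gene, had a log2 fold change of 3.83 ± 0.39. Against control replicate 1 alone and control replicate 2 alone the list's median was 3.01 and 2.90. It differed more with the BC2059 library used, at 2.415 without BC2059 replicate 2 and 3.356 without BC2059 replicate 1.

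All 28 tested NF-kB and inflammatory genes had a positive log2 fold change (camera adjusted p = 2.12e-23, and adjusted p = 0.221 with an estimated correlation). Of these, 23 passed as higher adjusted over the list alone, against 0 over all genes. CD83, a surface marker of activated antigen-presenting cells, averaged 50.7 ± 5.81 FPKM in BC2059 and 3.66 ± 0.957 in controls. TNFAIP2, a TNF-induced gene, averaged 316 ± 24.8 in BC2059 and 62.5 ± 2.91 in controls. The inflammatory list lay lower in control replicate 1 than in control replicate 2, by a median log2 difference of -0.55.

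Of 24 tested cholesterol biosynthesis genes, 23 had a positive log2 fold change (camera adjusted p = 1.84e-21, and adjusted p = 0.221 with an estimated correlation). In limma, 22 passed as higher adjusted over the list alone and 0 over all genes. LSS, which encodes lanosterol synthase, averaged 170 ± 5.18 FPKM in BC2059 and 36.8 ± 3.10 in controls. HSD17B7, another enzyme of the pathway, averaged 71.1 ± 1.89 and 15.9 ± 1.496. Their log2 fold changes were 2.18 ± 0.22 and 2.10 ± 0.22 (SE). This list too lay lower in control replicate 1 than in control replicate 2, with a median difference of -0.55.

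The unfolded protein response and ATF4 target list had a median log2 fold change of 0.76, with 29 of 35 members above 0 (camera adjusted p = 8.49e-10, and adjusted p = 0.221 with an estimated correlation). Higher members numbered 11 adjusted over the list alone and 0 over all genes. ATF3, a stress-induced transcription factor, averaged 39.2 ± 0.0875 FPKM in BC2059 and 1.72 ± 0.610 in controls. DDIT3, which encodes the stress-induced factor CHOP, averaged 47.6 ± 1.99 and 7.62 ± 3.04. ATF3 also belongs to the p53 target and immediate early gene lists.

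Both apoptosis lists, of opposing action, passed camera's threshold as higher groups with a preset correlation. Of 9 anti-apoptotic genes, 7 had a positive log2 fold change, with a median of 0.82 (camera adjusted p = 0.00160, and adjusted p = 0.221 with an estimated correlation), and 3 passed as higher when adjusted over the list alone, against 0 over all genes. BCL2A1 averaged 41.8 ± 1.17 FPKM in BC2059 and 7.48 ± 3.48 in controls, and BIRC3 averaged 66.1 ± 3.66 and 17.6 ± 11.2. Both also belong to the NF-kB list. Of 20 pro-apoptotic genes, 14 had a positive value, with a median of 0.38 (camera adjusted p = 0.0277, and adjusted p = 0.325 with an estimated correlation), and 0 passed when adjusted over the list alone in limma or over all genes, with 6 higher at an unadjusted p under 0.05. TNFSF10, which encodes the death ligand TRAIL and is also induced by interferon, had a log2 fold change of 3.81 ± 0.86 (SE), and PMAIP1, which encodes NOXA, 1.58 ± 0.38. TNFSF10 had 2.585 against control replicate 2 alone and 5.044 against control replicate 1 alone. The pro-apoptotic median was 0.06 against control replicate 2 alone and 0.72 against control replicate 1 alone.

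The p53 target list had a median of 0.42, with 20 of 27 members above 0 (camera adjusted p = 0.00472, and adjusted p = 0.325 with an estimated correlation). By limma, 2 passed as higher adjusted over the list alone and 0 over all genes. Its median was 0.11 against control replicate 2 alone and 0.66 against control replicate 1 alone. CDKN1A, the p53-induced cell cycle inhibitor p21, averaged 21.5 ± 0.109 FPKM in BC2059 and 6.72 ± 1.09 in controls. JAK-STAT target genes had a median of 0.47 over 19 members, 12 of them above 0 (camera adjusted p = 0.00804, and adjusted p = 0.221 with an estimated correlation), with 3 higher adjusted over the list alone and 0 over all genes. IL2RA, the alpha chain of the interleukin-2 receptor, averaged 240 ± 22.1 and 42.8 ± 5.26, and IL10RA had a log2 fold change of 1.60 ± 0.26. The JAK-STAT median was 0.16 against control replicate 2 alone. Against control replicate 1 alone it was 0.63 and the call was lost (camera adjusted p = 0.133).

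Immediate early genes, which cells induce within minutes of a stimulus, had a median of 0.37, with 18 of 25 members above 0 (camera adjusted p = 0.00231, and adjusted p = 0.466 with an estimated correlation). Adjusted over the list alone, 7 were higher and 1 lower, against 0 over all genes. NR4A3, an immediate early transcription factor, averaged 3.93 ± 0.348 FPKM in BC2059 and 0.129 ± 0.0744 in controls. The list lay higher in control replicate 1 than in control replicate 2, by a median of 1.14. With both controls and the GC trend removed, the list's median was 0.70. Its median was 0.93 against control replicate 2 alone, while against control replicate 1 alone the call was lost, with a median of -0.13 (camera adjusted p = 0.990).

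**Figure D2:**
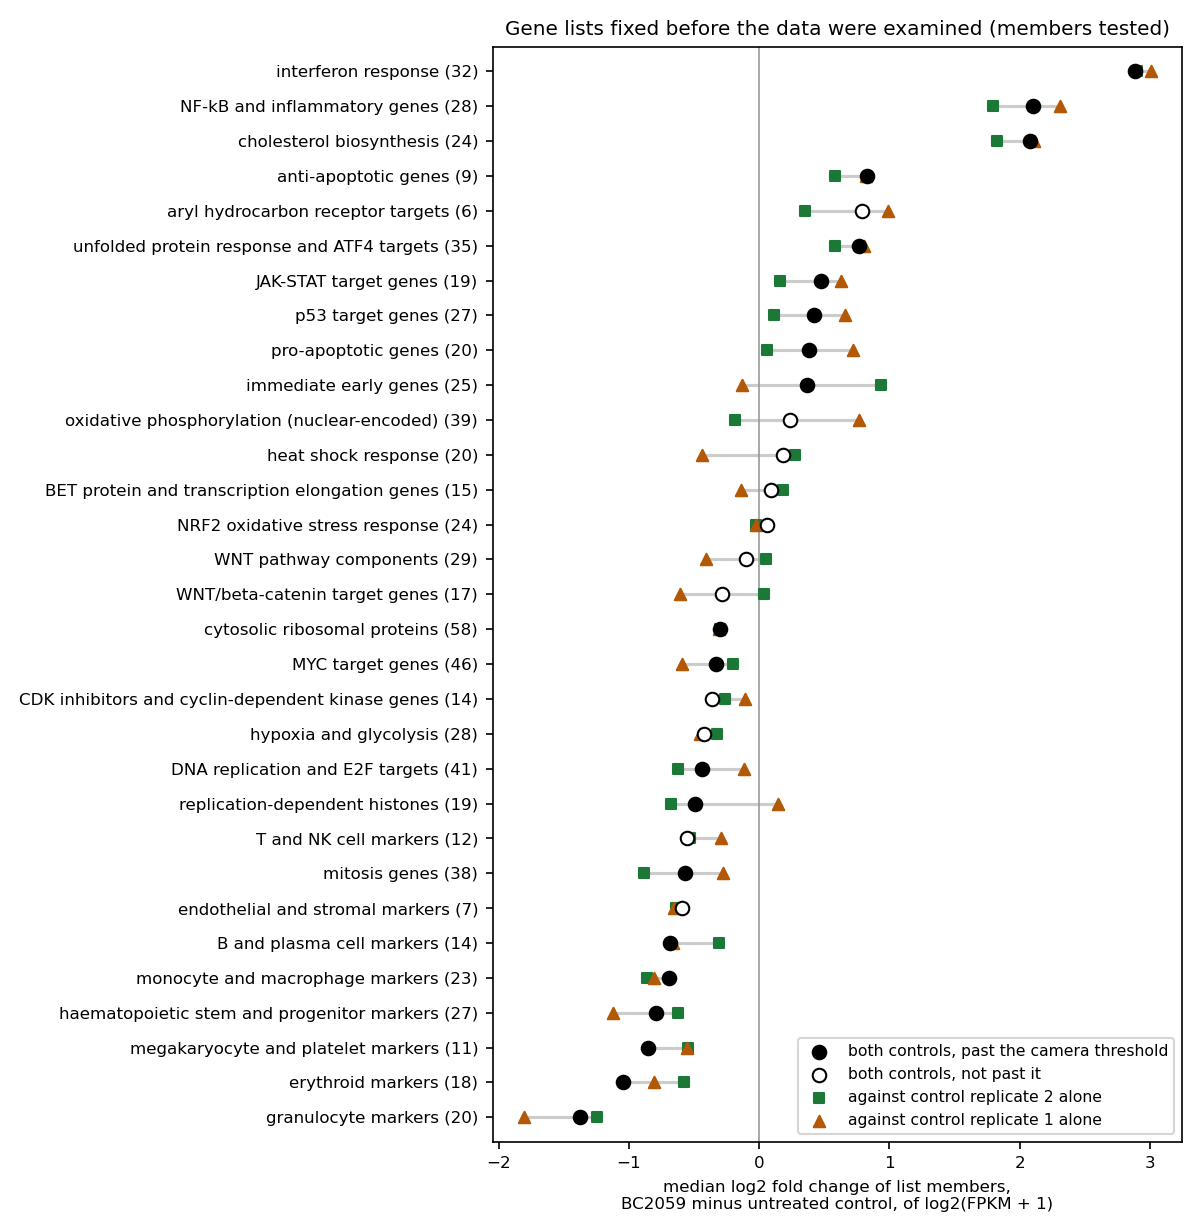
Each row is 1 of the 31 tested gene lists, and the horizontal axis is the median log2 fold change of its members, BC2059 minus untreated control. Circles use both controls (filled where camera's adjusted p was under 0.05), squares use control replicate 2 alone and triangles control replicate 1 alone. The interferon, NF-kB and cholesterol lists lie between 1.79 and 3.01 in all 3, and the immediate early genes lie on both sides of 0.

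Of 27 tested haematopoietic stem and progenitor markers, 25 had a negative log2 fold change, with a median of -0.79 (camera adjusted p = 2.92e-07, and adjusted p = 0.221 with an estimated correlation). By limma, 0 passed over all genes or adjusted over the list alone, and 12 were lower at an unadjusted p under 0.05. KIT, the stem cell factor receptor, averaged 26.02 ± 2.98 FPKM in BC2059 and 116 ± 57.3 in controls. FLT3, a receptor kinase often mutated in acute myeloid leukaemia, averaged 19.0 ± 2.67 and 43.8 ± 1.39. CD34 itself averaged 64.6 ± 1.26 and 150 ± 61.7, a log2 fold change of -1.14 ± 0.35 (adjusted p = 0.367), with -0.71 against control replicate 2 alone and -1.57 against control replicate 1 alone.

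Of 20 tested granulocyte markers, 19 had a negative log2 fold change (camera adjusted p = 5.57e-10, and adjusted p = 0.221 with an estimated correlation). Among them 8 passed as lower adjusted over the list alone, against 0 over all genes. CEACAM6, a granulocyte adhesion molecule, had a log2 fold change of -2.11 ± 0.31 (SE). DEFA3, which encodes a neutrophil defensin, had -2.44 ± 0.26, and its value is uncertain because near-identical defensin gene copies share reads. Monocyte and macrophage markers had a median of -0.69, with 19 of 23 members below 0 (camera adjusted p = 0.000200, and adjusted p = 0.221 with an estimated correlation). Adjusted over the list alone, 7 were lower and 1 higher, against 0 over all genes. VCAN, which encodes the proteoglycan versican, averaged 3.50 ± 0.127 FPKM in BC2059 and 17.2 ± 2.56 in controls, and CD163, a macrophage scavenger receptor, averaged 3.11 ± 0.402 and 19.4 ± 6.67.

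Erythroid markers had a median of -1.05, with 17 of 18 members below 0 (camera adjusted p = 2.62e-05, and adjusted p = 0.221 with an estimated correlation), and 2 were lower adjusted over the list alone, against 0 over all genes. The erythroid median was -0.57 against control replicate 2 alone. HBD, the delta-globin gene, averaged 9.01 ± 0.248 FPKM in BC2059 and 34.2 ± 11.7 in controls, and ANK1, of the red cell membrane skeleton, had a log2 fold change of -1.46 ± 0.29. Megakaryocyte and platelet markers had a median of -0.85 over 11 members, 8 of them below 0 (camera adjusted p = 0.0203, and adjusted p = 0.262 with an estimated correlation), with 1 lower adjusted over the list alone and 0 over all genes. ITGA2B, the platelet integrin alpha IIb chain, had a log2 fold change of -1.53 ± 0.26 and THBS1, thrombospondin 1, -1.65 ± 0.41. The megakaryocyte median was -0.54 against control replicate 2 alone, and the call was lost against control replicate 1 alone, at -0.56 (camera adjusted p = 0.133).

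B and plasma cell markers had a median of -0.69, with 10 of 14 members below 0 (camera adjusted p = 0.0436, and adjusted p = 0.446 with an estimated correlation). Adjusted over the list alone, 4 were lower and 2 higher, against 0 over all genes. DNTT, the terminal transferase of lymphoid precursors, averaged 2.60 ± 0.857 FPKM in BC2059 and 18.5 ± 4.38 in controls. CD22, a B cell surface lectin, went the other way, at 43.2 ± 17.7 and 6.06 ± 2.42. The list's call was lost without control replicate 1 (median -0.31, camera adjusted p = 0.102), without control replicate 2 (-0.66, 0.133) and without BC2059 replicate 2 (-0.50, 0.0920).

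Mitosis genes had a median log2 fold change of -0.57, with 36 of 38 members below 0 (camera adjusted p = 4.69e-07, and adjusted p = 0.318 with an estimated correlation). DNA replication genes and E2F targets had a median of -0.44, with 37 of 41 below 0 (camera adjusted p = 5.89e-06, and adjusted p = 0.221 with an estimated correlation). In each list limma called 0 members over all genes or adjusted over the list alone, with 12 mitosis and 14 replication genes lower at an unadjusted p under 0.05. MKI67, the gene of the proliferation antigen Ki-67, averaged 38.8 ± 1.39 FPKM in BC2059 and 134 ± 51.0 in controls, and TOP2A, topoisomerase II alpha, averaged 19.7 ± 2.76 and 63.1 ± 17.5. MCM4, a subunit of the replicative helicase, had a log2 fold change of -1.16 ± 0.31, and RRM2, of ribonucleotide reductase, -1.03 ± 0.21. Both lists lay lower in control replicate 1 than in control replicate 2, by medians of -0.60 and -0.47. Against control replicate 1 alone both calls were lost, with medians of -0.28 and -0.11 (camera adjusted p = 0.128 and 0.133), while against control replicate 2 alone the medians were -0.89 and -0.62.

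Replication-dependent histones had a median of -0.50, with 14 of 19 members below 0 (camera adjusted p = 0.00752, and adjusted p = 0.330 with an estimated correlation). By limma 0 passed over all genes or adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05. HIST1H2AE and HIST1H1B had log2 fold changes of -1.10 ± 0.27 and -1.14 ± 0.29, and values of single histone genes are uncertain because the copies are closely alike. The histone call was lost against control replicate 1 alone (median 0.14, camera adjusted p = 0.851), without BC2059 replicate 2 (-0.36, 0.145) and once the GC trend was removed (-0.19, 0.165).

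MYC target genes had a median of -0.33, with 39 of 46 members below 0 (camera adjusted p = 0.00393, and adjusted p = 0.221 with an estimated correlation). The median was -0.21 against control replicate 2 alone, -0.59 against control replicate 1 alone and -0.18 once the GC trend was removed. By limma 0 passed over all genes or adjusted over the list alone, with 4 lower and 1 higher at an unadjusted p under 0.05. LDHA, lactate dehydrogenase A, averaged 310 ± 14.2 FPKM in BC2059 and 694 ± 63.4 in controls. DUSP2, a phosphatase that is also an immediate early gene, went the other way, at 9.63 ± 0.911 and 2.20 ± 0.970. Cytosolic ribosomal protein genes had a median of -0.30, with 39 of 58 below 0 (camera adjusted p = 0.0203, and adjusted p = 0.221 with an estimated correlation), and by limma 0 passed either way, with 1 lower at an unadjusted p under 0.05. RPS16, the member with the smallest p, had a log2 fold change of -0.76 ± 0.25. The ribosomal direction flipped under cyclic loess normalization, with a median of 0.06. The ribosomal call was also lost against control replicate 1 alone (median -0.31, camera adjusted p = 0.161) and without BC2059 replicate 1 (-0.31, 0.0963) or BC2059 replicate 2 (-0.33, 0.253).

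Target genes and components of the WNT pathway did not differ between the groups past the threshold. Of 34 listed beta-catenin target genes, 17 reached the filter, and their median log2 fold change was -0.29, with 11 below 0 (camera adjusted p = 0.205, and adjusted p = 0.721 with an estimated correlation). The median was 0.04 against control replicate 2 alone and -0.055 with both controls once the GC trend was removed. Against control replicate 1 alone it was -0.61, past the threshold (camera adjusted p = 0.0297). AXIN2 and LEF1, feedback and effector genes of the pathway, stayed below 1 FPKM in every library. AXIN2 was listed at 0 in both controls and at 0.0309 and 0.0577 in the BC2059 libraries. LEF1 was listed at 0.655 and 0.384 in the controls and at 0.132 and 0.148 in the BC2059 libraries. JUN, another listed target, averaged 12.4 ± 0.536 in BC2059 and 2.53 ± 1.62 in controls. By limma, 0 targets passed over all genes or adjusted over the list alone, with 1 higher and 2 lower at an unadjusted p under 0.05.

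The 29 tested WNT pathway components had a median of -0.10 (camera adjusted p = 0.658, and adjusted p = 0.798 with an estimated correlation), with 0 called by limma either way and 1 lower at an unadjusted p under 0.05. The median was 0.05 against control replicate 2 alone and -0.41 against control replicate 1 alone. CTNNB1 (ENSG00000168036), the gene of beta-catenin itself, averaged 370 ± 3.98 FPKM in BC2059 and 202 ± 135 in controls, a log2 fold change of 1.05 ± 0.53 (adjusted p = 0.503). It was 0.31 against control replicate 2 alone and 1.79 against control replicate 1 alone. TBL1X, which encodes a binding partner of beta-catenin, had -0.44 ± 0.34 (adjusted p = 0.569), and -0.06 against control replicate 2 alone. FOXM1, a proliferation-linked transcription factor, had -1.60 ± 0.44, and LRP5, a WNT coreceptor, -1.88 ± 0.78. Against control replicate 2 alone they had -1.05 and -0.74. TCF7L2, a DNA-binding partner of beta-catenin, had 0.49 ± 0.58 and turned to -0.32 against control replicate 1 alone.

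MYC had a log2 fold change of -1.52 ± 0.37 (SE, adjusted p = 0.297), with -1.06 against control replicate 2 alone and -1.98 against control replicate 1 alone. CCND1, cyclin D1, had -0.99 ± 0.56 (adjusted p = 0.515), and -0.23 against control replicate 2 alone. CDK6, a kinase that drives entry into S phase, averaged 176 ± 9.05 FPKM in BC2059 and 344 ± 111 in controls, a log2 fold change of -0.93 ± 0.32, and -0.59 against control replicate 2 alone. CDK4, its close relative, had -0.26 ± 0.50, and turned from -0.95 against control replicate 2 alone to 0.43 against control replicate 1 alone. PIM1, a kinase gene induced by STAT factors, averaged 72.4 ± 12.9 and 23.9 ± 14.1, a log2 fold change of 1.68 ± 0.46, and 1.06 against control replicate 2 alone. MCL1 and BCL2L1, anti-apoptotic genes, had 1.01 ± 0.38 and 0.70 ± 0.26, whereas BCL2 had -0.79 ± 0.43. Against control replicate 2 alone MCL1 had 0.54 and BCL2 -0.28. CDKN1B, the cell cycle inhibitor p27, had -0.74 ± 0.35, and -0.33 against control replicate 2 alone. BIRC5, which encodes survivin, had -0.19 ± 0.32, and turned to 0.09 against control replicate 1 alone. HEXIM1, a regulator of transcription elongation, had -0.55 ± 0.53, and turned to 0.18 against control replicate 2 alone.

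**Figure D3:**
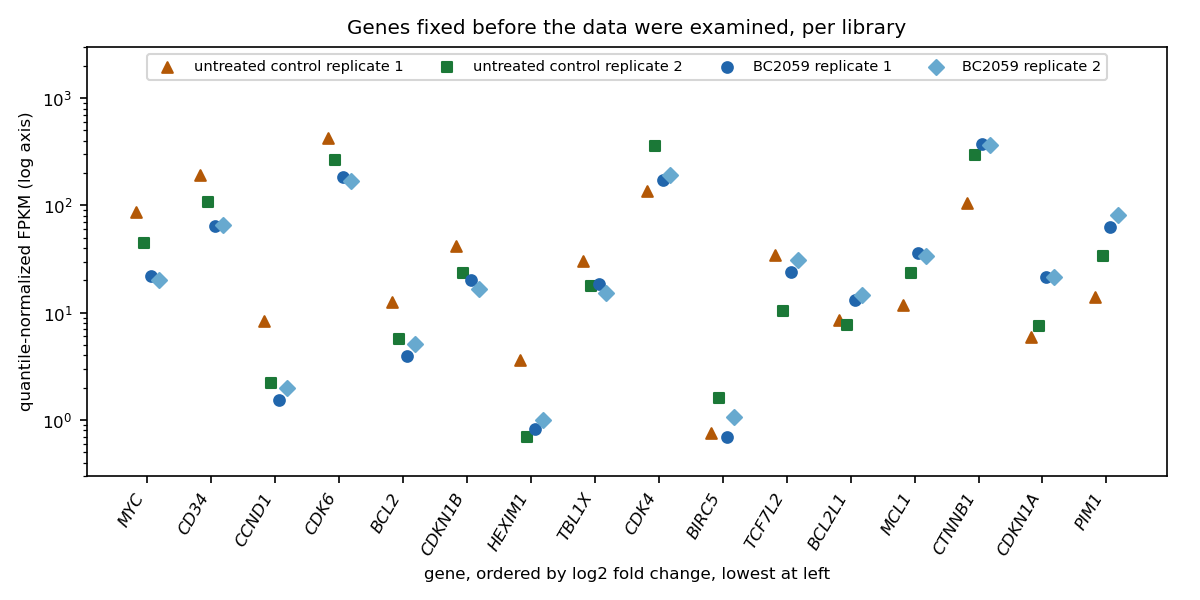
The plot shows quantile-normalized FPKM on a log axis for 16 genes fixed before the data were examined, with 1 point per library. MYC lies at 21.9 and 20.3 in the BC2059 libraries and at 86.0 and 45.1 in the controls, and HEXIM1 is at 3.64 in control replicate 1 and at 0.689 to 0.996 in the other 3 libraries.

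The remaining lists did not pass camera's threshold. Hypoxia and glycolysis genes had a median of -0.42 over 28 members (camera adjusted p = 0.125), where GPI, a glycolytic enzyme, averaged 45.8 ± 3.62 FPKM in BC2059 and 89.6 ± 10.7 in controls. T and NK cell markers had a median of -0.56 over 12 members (0.0587), with PRF1, perforin, at -1.08 ± 0.26 and LCK at -1.55 ± 0.40. This T and NK list passed against control replicate 2 alone (median -0.53, camera adjusted p = 0.0432) and not against control replicate 1 alone (-0.29, 0.229). Endothelial and stromal markers had a median of -0.60 over 7 members (0.115), with FN1, fibronectin, at -0.85 ± 0.24 and TEK at -0.93 ± 0.29. The 14 cyclin-dependent kinase and inhibitor genes had a median of -0.36 (0.309), or -0.11 against control replicate 1 alone, and CDKN1A was the 1 member that passed adjusted over the list alone.

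Heat shock genes had a median of 0.18 over 20 members (camera adjusted p = 0.210), and DNAJB1 and HSPA6, inducible chaperones, had log2 fold changes of 1.57 ± 0.22 and 2.00 ± 0.32. The heat shock list passed against control replicate 2 alone (median 0.27, camera adjusted p = 0.000475) and had a median of -0.44 against control replicate 1 alone. NRF2 oxidative stress genes had a median of 0.06 over 24 members (0.656), which turned to -0.03 and -0.02 against control replicates 2 and 1 alone, with SQSTM1, an autophagy receptor, at 470 ± 10.9 FPKM in BC2059 and 110 ± 9.66 in controls, and ME1, malic enzyme, at a log2 fold change of 1.45 ± 0.40. Aryl hydrocarbon receptor targets had a median of 0.79 over 6 members (0.144), or 0.35 against control replicate 2 alone, and TIPARP and CYP1A1, both induced by that receptor, had 1.27 ± 0.31 and 0.98 ± 0.25. Adjusted over the list alone, 3 of these 6 were higher and 1 lower, 2 heat shock genes were higher and 1 NRF2 gene was higher, against 0 over all genes.

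Nuclear-encoded oxidative phosphorylation genes had a median of 0.24 over 39 members (camera adjusted p = 0.294), while NDUFB10 and COX8A, the members with the smallest p, had -0.64 ± 0.23 and -0.63 ± 0.24. That list was lower against control replicate 2 alone (median -0.18, camera adjusted p = 0.00799) and higher against control replicate 1 alone (0.77, 0.00301). The 15 BET protein and transcription elongation genes had a median of 0.09, a mean of -0.03 and a camera direction of higher (adjusted p = 0.473), and ELL2, an elongation factor, had 1.24 ± 0.28 and MED13 0.57 ± 0.25. Against control replicate 2 alone the BET list was past the threshold as higher, with a median of 0.18 (camera adjusted p = 0.0172).

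By limma, the genes with the smallest p among those higher in BC2059 were the chemokine genes CCL3L3 and CCL3L1, then ATF3, OAS1, CSF2 and CD83. CCL3L3 averaged 146 ± 14.04 FPKM in BC2059 and 7.61 ± 1.45 in controls, and CCL3L1 averaged 192 ± 26.2 and 9.92 ± 2.73. These copies of CCL3 are near-identical, so their separate values are uncertain. CSF2, which encodes the growth factor GM-CSF, averaged 39.8 ± 12.02 and 1.44 ± 0.124. Among the lower genes, DEFA3 had the smallest p, followed by TGFBI, AK5, MS4A6A, VCAN and SORL1. TGFBI, a matrix protein gene induced by TGF-beta, averaged 2.33 ± 0.432 in BC2059 and 16.4 ± 1.89 in controls. AK5, an adenylate kinase, had a log2 fold change of -2.67 ± 0.34, MS4A6A -2.23 ± 0.28 and SORL1, a sorting receptor, -1.66 ± 0.23. The smallest adjusted p was 0.118, shared by 47 genes.

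Both BC2059 libraries lay above both controls in 2841 genes and below both in 3115, which together are 51.9% of the tested genes. The controls lay far apart and the BC2059 libraries close together, so both controls can often fall on the same side without an effect. How often exactly is unknown here, and these counts are no sign of an effect. With limma on simulated values that had the pooled spread of these libraries, 0% of genes changed by a log2 of 1 were recovered, 2.99% of those changed by 2 and 78.8% of those changed by 4. With the spread of the 2 BC2059 libraries in its place, the shares were 85.1%, 95.5% and 100%.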

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

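GC removal and library weights were chosen after the data were seen. The count of 0 genes in each direction held with both other pseudocounts, both other filters, cyclic loess, median-of-ratios scaling, no trend, robust estimation, the test against a fold of 1.2 and GC removal, where the smallest adjusted p ranged from 0.0567 to 0.316. With library weights limma called 37 genes higher and 1 lower, giving each control a weight of 0.226 and each BC2059 library 4.43. With each library left out in turn it called 54 to 3592 genes higher and 1 to 3823 lower. The most came without control replicate 2, and without control replicate 1 there were 720 higher and 984 lower. These fits keep 1 residual degree of freedom. A lone control is assumed to vary like the BC2059 pair, and a lone BC2059 library like the pair of controls. Against each control alone, 560 genes were higher and 665 lower in both fits, where independent lists would share 225 and 328, and 123 were called in opposite directions. In 20 simulations of unchanged genes, which share the BC2059 libraries, the counts ranged from 473 to 589 and from 411 to 629. The observed higher count lies within its range and the lower count above it. Both simulated controls had the same spread, shuffled over genes, whereas control replicate 1 lay farther from the BC2059 libraries than control replicate 2. The simulations therefore cannot decide whether the shared counts exceed those of unchanged genes. With the replicate number as a block, 317 genes were higher and 355 lower, on 1 residual degree of freedom. The deviations of same-numbered libraries correlated at 0.0725 across genes. The large difference between the controls could mask a shared effect, so this does not show whether the numbers pair the libraries.

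The gene lists called numbered 9 higher and 11 lower, and 8 to 11 higher over the alternatives. Leaving out each library gave 6 to 12 lower. With no filter the pro-apoptotic, ribosomal and megakaryocyte calls were lost, with the block the ribosomal call, with library weights the B cell call and with GC removal the histone call. Hypoxia genes gained a call with a mean of at least 5, and T and NK markers with GC removal or library weights. The choices without trend, with robust estimation and of a fold of 1.2 give no list values. Medians turned sign, or camera its direction, for ribosomal proteins under cyclic loess (0.059) and for NRF2 genes with a mean of at least 5 (0.11). WNT components (0.14) and the BET median (-0.037) turned with GC removal. Directions also turned with a library left out. Over those fits WNT targets ranged from -0.61 to 0.038, WNT components from -0.41 to 0.048, oxidative phosphorylation from -0.18 to 0.77, heat shock from -0.44 to 0.27, NRF2 genes from -0.028 to 0.14, immediate early genes from -0.13 to 0.93, histones from -0.68 to 0.14 and BET genes from -0.14 to 0.18. Among genes, HEXIM1 ranged from -1.28 to 0.18, TCF7L2 from -0.32 to 1.30, BIRC5 from -0.48 to 0.092, CDK4 from -0.95 to 0.43, MT2A from -0.69 to 2.06 and MT-ND3 from -0.46 to 0.23. Their causes were not tested. The unknown depth limits what can be said of genes near 1 FPKM.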

Other observations

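The gene families and the tests of explanations below were chosen after the data were seen. Genes were grouped by the letters that start their symbols, which gave 174 families of at least 8 tested genes, and 7 families passed camera's threshold. Chemokine genes of the CCL family (15) had a median log2 fold change of 1.31, with 12 above 0 (camera adjusted p = 2.74e-06). CCL4 was listed at 504 and 557 FPKM in the BC2059 libraries and at 12.7 and 40.3 in the controls. Interferon-induced IFI genes (8) had a median of 1.44 with 6 above 0 (camera adjusted p = 0.00200), and DNAJB chaperone genes (9) a median of 0.62 with 8 above 0 (0.00262). HLA genes, which encode antigen-presenting molecules (19), had a median of 0.88 with 13 above 0 (0.0252). ZNF zinc finger genes (435) had a median of 0.19 with 293 above 0 (0.0363). HIST histone genes (61) had a median of -0.62 with 52 below 0 (3.11e-08), and MCM genes (10), mostly of the replicative helicase, a median of -0.63 with 9 below 0 (0.0237). The fixed lists already held 5 of the IFI, 7 of the MCM, 19 of the HIST, 4 of the CCL and 3 of the DNAJB genes. Those families are therefore not independent of the lists. With an estimated correlation the adjusted p of each family was 0.995. No family values are given with the GC trend removed. The fixed histone list lost its call under that removal (median -0.19, camera adjusted p = 0.165). Against control replicate 1 alone the CCL (0.0299) and ZNF (0.0344) families passed and the other 5 were lost (0.240 to 0.310). Against control replicate 2 alone ZNF did not (0.367). Against control replicates 2 and 1 alone the medians were 0.49 and 1.17 for HLA, 0.05 and 0.37 for ZNF, 1.13 and 1.48 for CCL, 1.61 and 1.31 for IFI, 0.54 and 0.78 for DNAJB, -0.91 and -0.49 for HIST, and -0.72 and -0.76 for MCM.

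SLFN5, an interferon-induced gene outside the fixed lists, was at 62.6 and 124 FPKM in the BC2059 libraries and at 3.07 and 6.11 in the controls. CXCL11, which encodes a chemokine, was at 9.39 and 21.7 FPKM and at 0 and 0.467. TRIM22, an antiviral gene, was at 254 and 427 FPKM against 75.4 and 85.6. HOXA9, a homeobox gene active in leukaemia, was listed lower, at 11.7 and 12.9 FPKM against 51.9 and 21.5. None of these 4 genes passed limma's test over all genes, and they were picked after their values were seen.

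Untreated control replicate 1 stood apart from the other 3 libraries. A bias in GC content is a candidate cause of part of this, since the difference between the controls correlated with GC at r = 0.544 across genes, against at most 0.187 among pairs of the other 3 libraries. A smooth trend with 1 GC value per gene does not account for the whole. Once it was taken out, the SD of that difference was still 0.742, above the largest SD of any pair of the other 3 libraries (0.578). The GC value was a mean over a gene's annotated transcripts and may miss part of such a bias. GC content as the whole cause is therefore not excluded. Red blood cell RNA is argued against by HBB, HBD, HBG1 and HBG2, whose median was -0.76 in control replicate 1 minus 2 while HBA1 and HBA2 averaged 3.51, and an exchange with a treated library by the interferon list, at -0.20 against 2.90 for BC2059. The rest of the difference stays open, and no biological explanation was tested because the design gives none within a group.

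The interferon, NF-kB and cholesterol lists were higher in BC2059. The departure of control replicate 1 does not explain them, since the lowest of the 3 medians was still 1.79 without that library, and neither does GC content, with a lowest median of 2.07 after GC removal. More monocytes or macrophages in the treated cultures were predicted to raise the markers of those cells. The median of these markers was -0.69, and LYZ, the most abundant of them, had a log2 fold change of -1.38. Such values cannot tell the share of cells from the transcripts in each cell, so they do not decide on this explanation. No test separate from the comparison itself bears on a response to BC2059, so the cause of the 3 lists stays open.

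The progenitor, granulocyte, monocyte, erythroid, mitosis and replication lists were lower in BC2059. A lower share of CD34-positive progenitors was predicted to raise the markers of other cells, but the highest median among the granulocyte, monocyte and erythroid lists was -0.69. Those lists also hold genes that progenitors can express, such as MPO and GATA1, so they cannot decide on this explanation. The departure of control replicate 1 does not explain the pattern as a whole, since without that library the highest of the 6 medians was -0.57, and after GC removal it was -0.42. Against control replicate 1 alone the mitosis and replication calls were lost, with medians of -0.28 and -0.11. After GC removal with both controls both calls held, with medians of -0.62 and -0.42. How far those lists depend on 1 control is therefore not settled. No test separate from the comparison itself bears on a response to BC2059, so the cause of all 6 lists stays open.

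The 4 libraries can be split into 2 and 2 in 3 ways, which is too few for a share under 0.05. The real split gave 20 gene lists past camera's threshold and was the 1 split with so many, and the highest of the others gave 6.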
